A study of Mus musculus with 7 samples.

How the data were processed

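The deposited tables are count matrices of unique molecular identifiers (UMIs) per gene and barcode, which the authors made with Cell Ranger 5.0.1 on the mouse genome mm10, per the submitters' processing notes. The 7 matrices used were 3 from blood, 2 from heart and 2 from brain, each from a pool of 5 mice taken on day 3 after surgery. Per the labels, blood was drawn behind the eye and its red cells were lysed, heart cells came from the infarct and were enriched for CD45 with magnetic beads, and brain cells were cleaned on a density gradient and then enriched for CD45. The brain sham matrix held exactly 2000 barcodes; whether it was cut at a set number is not known, and if so the brain shares of cells with few UMIs would depend on that cut. Of 32285 features, 32235 matched the GENCODE vM21 annotation (GRCm38), which gave the gene positions.

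Main results, comparisons and alternatives were chosen before the data were examined, and 9 further alternatives were added after seeing the data. Barcodes were kept with at least 200 genes and at most 10% mitochondrial UMIs, which left 17.1%, 16.9% and 16.3% of blood barcodes (sham, MI, MI+SF), 96.0% and 93.1% of heart barcodes (MI, MI+SF) and 94.5% and 97.0% of brain barcodes (sham, MI). Doublets were called with scrublet in each library. Its automatic threshold called 1, 0 and 1 cells in blood, 1 and 0 in heart and 7 and 0 in brain, where 4.75%, 5.12%, 5.65%, 10.0%, 5.54%, 1.51% and 8.31% of cells were expected, so the caller did not work here. Called cells were left out, and as an alternative the cells with the highest scores were left out up to the expected rate.

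Libraries of a tissue were put together without integration, scaled to 10000 UMIs per cell and log transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1 with seed 0. Clusters were named with 26 sets of marker genes, a cluster that matched no set clearly stayed unnamed, and unnamed leukocyte clusters count only in the denominator of shares. The unnamed clusters held 8.82%, 15.0% and 9.10% of blood leukocytes and 8.43% and 10.7% of heart leukocytes. Leukocytes numbered 4955, 5193 and 5814 in blood, 16092 and 6723 in heart and 1299 and 6489 in brain.

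Shares have exact Clopper-Pearson intervals. For genes, UMIs were summed over all cells of a class in a library and divided by the total of the class, and the ratio of a pair of libraries has an exact Poisson interval. For gene lists, the median log2 ratio over members with at least 10 summed UMIs was taken, with an interval from 200 Poisson redraws and a percentile among 10000 random lists matched on expression in 20 bins. A ratio against 0 was given as a lower limit, with a floor of 3 counts per library. Classes with at least 50 cells in both libraries were used. With 1 library per group no test was made, no gene was called as changed, and differences between tissues were not tested.

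There were 17 gene lists: interferon response, inflammatory cytokines and NF-kB feedback, alarmins and neutrophil granules, neutrophil maturation and trafficking, MHC class II presentation, resident and reparative macrophage, lipid-associated and wound macrophage, hypoxia and glycolysis, cell cycle, glucocorticoid response, circadian clock, receptors for sleep, stress and autonomic signals, dissociation and immediate early genes, microglia homeostasis, disease-associated microglia, cytotoxic lymphocyte and ribosomal proteins. Lists in the outer 5% of random lists on either side, and those that the question names, are reported. In each comparison genes were named in the 2 named leukocyte classes with the most cells in the smaller library. Up to 6 genes per direction were taken by the interval bound nearest to no difference, with at least 50 UMIs in the higher library and a level of at least 0.2 of that in the class where the gene is highest. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, sex chromosome marker and predicted genes were left out. Also named were up to 4 members with the largest ratio of each reported list, and Tnf, Il1b, Il6, Ccl2, Ccr2, Cxcl2 and Nr3c1, and 1 further gene set beforehand that is not reported here.

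Alternatives set beforehand were resolution 2.0, each cell weighted equally, the class of a cell from its own marker score, all kept cells as denominator, doublets kept, at most 20% mitochondrial UMIs, at least 100 or 500 genes per barcode, list members with at least 1 UMI, and scaling by the median ratio of all genes. The 9 added ones were leaving out the highest doublet scores, leaving haemoglobin out of totals, thinning cells to 1000 UMIs, leaving microglia out of the denominator, counting the B and platelet cluster outside leukocytes, leaving out the 2 cells with the most UMIs of a gene, applying the filters to further shares and lists, giving the clusters of a class equal shares of cells or of UMIs in both libraries (clusters with under 20 cells in a library left out), and leaving out of list medians the 0.2% of cells, or the 2 cells, with the most UMIs of each gene.

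The gene and list steps were tried on simulated counts with 200 changed genes. These counts were Poisson draws around the summed counts, so interval coverage near 95% was built in. Clumping of UMIs in single cells and differences between mice were not simulated, so the trial checks only the calculation. In blood neutrophil-like cells, 3787 genes (MI against sham) and 3747 genes (MI+SF against MI) had intervals that covered the true value for 95.5% and 95.9%, and a list shifted by 0.5 was recovered at 0.518 and 0.477. In heart macrophage-like cells, 11462 genes gave 95.4% and 0.497. In brain microglia-like cells, 10047 genes gave 95.4% and 0.529.

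The software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9. Free RNA was not removed from the counts. Heart cells of sham mice were not analysed here.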

Results

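Single-cell RNA sequencing with 5' droplet libraries was used to profile leukocytes of blood, heart and brain from adult female mice 3 days after sham surgery or myocardial infarction (MI), which was made by permanently tying a coronary artery. In the MI+SF group, sleep was also broken up every day during the light period (sleep fragmentation, SF). Each of the 7 libraries held pooled cells of 5 mice, and every combination of tissue and group had 1 library: blood of sham, MI and MI+SF mice, heart of MI and MI+SF mice, and brain of sham and MI mice. Heart cells of sham mice were not analysed here. There were no replicate libraries, so no value below has an error between replicates. All intervals are 95% intervals that cover counting error only, and a difference between 2 libraries describes those libraries.

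The blood libraries held 34761 (sham), 37933 (MI) and 43359 (MI+SF) barcodes with 56067693, 59826028 and 59245426 unique molecular identifiers (UMIs), of which haemoglobin transcripts took 76.5%, 77.6% and 79.2%. After filtering, 5934, 6406 and 7061 barcodes were kept, with a median of 1990.5, 1910.5 and 1612 UMIs. The heart libraries held 17241 (MI) and 7434 (MI+SF) barcodes with 89640384 and 54293969 UMIs, and 16552 and 6921 were kept at a median of 4209 and 5761 UMIs. The brain libraries held 2000 (sham) and 10704 (MI) barcodes with 4924670 and 38798414 UMIs, and 1883 and 10385 were kept at a median of 1281 and 1531 UMIs. Clustering gave 12 clusters in blood, 23 in heart and 25 in brain, which were named from marker genes and are called neutrophil-like, B-like and so on.

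**Figure D1:**
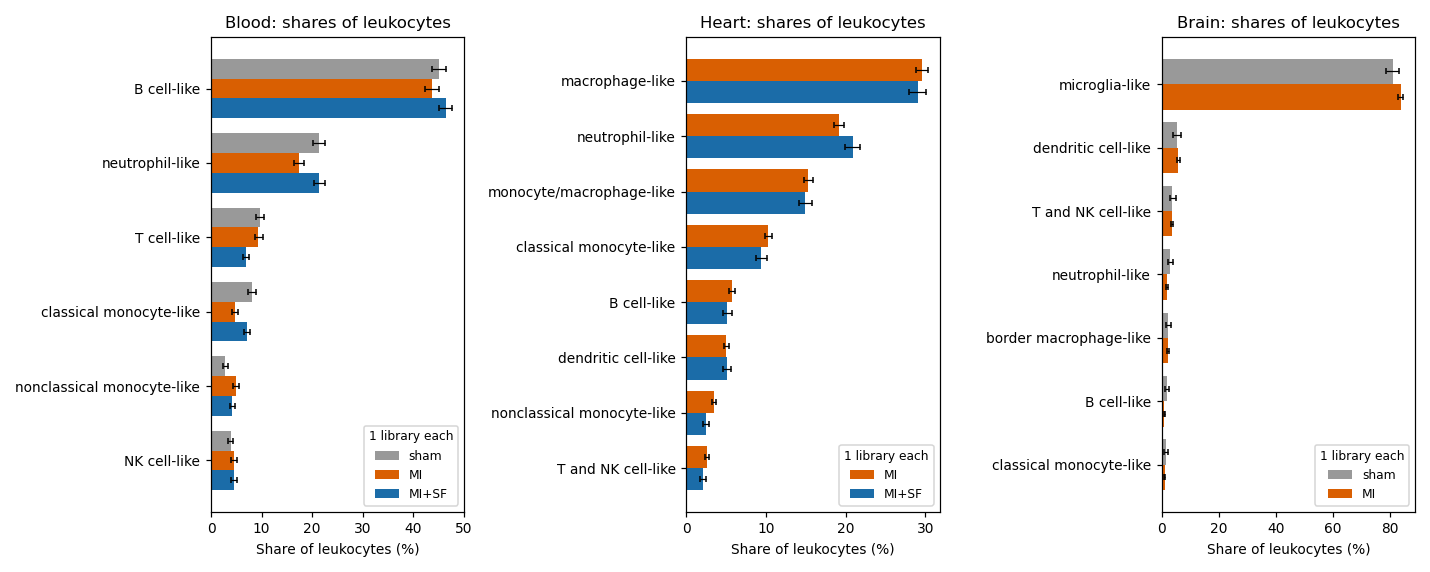
Percent of leukocytes in each named class, on a horizontal axis, in blood (sham, MI, MI+SF), heart (MI, MI+SF) and brain (sham, MI); bars are single pooled libraries and lines are exact 95% Clopper-Pearson intervals. Classical monocyte-like cells made up 8.07%, 4.72% and 7.07% of blood leukocytes in sham, MI and MI+SF, while microglia-like cells held 80.9% and 83.6% of brain leukocytes in sham and MI.

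The comparison of blood after MI with blood after sham surgery asks which circulating immune cells go with an infarct. Classical monocyte-like cells, the Ccr2-bearing monocytes that enter inflamed tissue, made up 8.07% of leukocytes in the sham library (400 cells; interval 7.33 to 8.87%) and 4.72% in the MI library (245 cells; 4.16 to 5.33%), 0.584-fold the sham share (log2 ratio -0.77, interval -0.997 to -0.55). Nonclassical monocyte-like cells, which patrol vessel walls, were higher, at 2.81% in sham and 4.93% in MI (log2 ratio 0.81, interval 0.52 to 1.11). Neutrophil-like cells took 21.3% of leukocytes in sham and 17.4% in MI (log2 ratio -0.29, interval -0.41 to -0.18). This class held 1055 sham and 904 MI cells, but 314 and 233 when each cell was classed by its own markers. In UMIs summed over each class, immediate early genes were lower after MI in 5 classes. Inflammatory and granule genes were lower in the neutrophil-like class, and interferon response genes in T-like cells and in the B-like class as a whole. For the neutrophil-like class, lower levels per cell were not told apart from a differing makeup of the class.

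B-like cells were 45.0% of leukocytes in sham and 43.6% in MI, T-like cells 9.67% and 9.38%, and NK-like cells 3.85% and 4.45%. An unnamed cluster with both B cell and platelet markers held 8.82% and 15.04%, and platelet-like barcodes were 8.26% and 11.9% of all kept barcodes. The 11 blood clusters of at least 100 cells differed in share by a median absolute log2 ratio of 0.33, where counting error alone gives 0.06.

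Several genes were named as lower in neutrophil-like cells of the MI library. Ifitm6, a membrane protein of myeloid cells (GRCm38 chromosome 7, 141015699 to 141017924), stood at 118 CPM (UMIs scaled to the total of the class) in MI and 414 in sham, 0.285-fold (interval 0.243 to 0.333). Lrg1, a granule and plasma glycoprotein (chromosome 17, 56119678 to 56122001), stood at 563 and 1302 CPM, 0.433-fold (0.401 to 0.466). Ly6g, the surface marker of mouse neutrophils (chromosome 15, 75155240 to 75159126), was 0.408-fold (0.326 to 0.508). The receptor gene Lilr4b was 0.437-fold, Acod1, which makes itaconate, 0.270-fold and the scramblase Plscr1 0.261-fold. The genes named as higher were Psmb8, a subunit of the immunoproteasome, at 1.69-fold (1.39 to 2.05), the glucocorticoid-induced chaperone partner Fkbp5 at 1.93-fold (1.34 to 2.82), Ntan1 at 2.56-fold and Gpr141 at 2.58-fold. The granule genes Camp and Ngp also met the size rule, but 89 of 89 Camp UMIs and 124 of 138 Ngp UMIs of the MI library lay in 1 cell, and without the 2 cells with the most Ngp UMIs in each library its log2 ratio was -2.24.

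Inflammatory cytokine and NF-kB feedback genes were lower in neutrophil-like cells of the MI library, with 16 of 20 measured members lower and a median log2 ratio of -0.31 (interval -0.56 to -0.11; percentile 0.15 among matched random lists). Nfkbia, the inhibitor that NF-kB itself induces, was 0.574-fold and the fungal pattern receptor Clec4e 0.655-fold. Alarmins and neutrophil granule genes had 12 of 16 members lower and a median of -0.30 (-0.39 to -0.21), below all 10000 random lists, with Lcn2, an iron-scavenging granule protein, at 0.548-fold. Interferon response genes had 13 of 21 members higher and a median of 0.20 with an interval that includes 0 (-0.02 to 0.37; percentile 97.9). Isg15, a ubiquitin-like interferon product, was 1.36-fold and Irf7, a transcription factor of the interferon loop, 1.34-fold, while Ifitm3 was 0.814-fold. The lipid and wound list (-0.35, 8 of 11 lower), the hypoxia and glycolysis list (-0.17, 11 of 18 lower, with the glucose transporter Slc2a1 at 0.362-fold) and the disease-associated microglia list, whose measured members here include Apoe and Lgals3 (-0.11, 7 of 12 lower), also stood in the lower 5%. Haemoglobin took 45.4% of the UMIs of these cells in MI and 43.2% in sham, 8 platelet marker genes together were 1.32-fold in MI, and 9 classical monocyte markers together were 0.751-fold (1343 against 1789 CPM).

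In B-like cells of the MI library Cd69, an early activation marker (chromosome 6, 129267325 to 129275436), was 0.604-fold (interval 0.529 to 0.689), Fosb 0.547-fold and Isg15 0.569-fold. Interferon response genes had 18 of 22 members lower (median -0.24, -0.49 to -0.12; percentile 0.75), with Rtp4 at 0.512-fold and Rsad2 at 0.720-fold. Cluster 6, which interferon genes lead, held 4.08% of B-like cells in sham and 2.69% in MI. Within clusters the list was -0.66 in cluster 6 (-0.97 to -0.23), and in the much larger clusters 1 (-0.20, -0.38 to 0.06) and 4 (-0.08, -0.32 to 0.12) its interval included 0. All 12 MHC class II presentation genes, which load and display antigen peptides, were lower by a small amount (median -0.11, -0.16 to -0.08), among them the invariant chain Cd74 at 0.901-fold. Mtmr6 (0.383-fold), Cox18 (0.398-fold) and Tdp2 (0.492-fold) were the other genes named as lower. St13 (1.52-fold), Bahd1 (1.84-fold), Opa1, a fusion protein of the inner mitochondrial membrane (1.84-fold), Lzic (1.78-fold) and Smim27 (1.58-fold) were among those named as higher, on 33 to 238 UMIs per library. The cell cycle list (0.10) and the ribosomal protein list (0.02, 14 of 19 higher) stood in the upper 5%.

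Immediate early and dissociation genes, which include the AP-1 factors and heat shock genes that respond within minutes to stimulation or handling, were lower after MI in B-like (13 of 16 members, median -0.26), T-like (11 of 13, -0.24), classical monocyte-like (15 of 19, -0.28), neutrophil-like (15 of 18, -0.25) and nonclassical monocyte-like cells (13 of 15, -0.37). Fos was 0.409-fold in B-like cells (23.4 against 57.2 CPM) and 0.710-fold in classical monocyte-like cells, and Jun was 0.590-fold in the latter. In nonclassical monocyte-like cells the median of all genes was itself shifted by -0.15, and against that shift the list stood at -0.23. Haemoglobin took 34.6% of the UMIs of these cells in MI and 27.5% in sham, which alone gives a shift of -0.15. There, 9 of 9 alarmin and granule genes were lower (median -1.95, or -1.80 against the shift), with S100a8 at 0.186-fold, and 123 of its 361 sham UMIs lay in 1 cell; 14 neutrophil markers together were 0.272-fold there. The glucocorticoid response list was higher in these cells (0.19, 6 of 10 members), with Ddit4 at 0.585-fold and Txnip at 1.40-fold.

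In classical monocyte-like cells, the glucocorticoid response list, which reads the transcriptional effect of stress steroids, had 9 of 14 members lower and a median of -0.13 (-0.40 to 0.20), at percentile 14.2, so no difference was detectable at this depth. The inflammatory list did not differ detectably there (median -0.20, -0.38 to 0.11; 10 of 18 members lower), though Clec4e was 0.562-fold. Ccr2, the receptor that draws monocytes out of marrow and blood (chromosome 9, 124101950 to 124113557), was 544 CPM in MI and 692 in sham, 0.786-fold (0.708 to 0.871). Tnf (0.390-fold) and Ccl2 (0.473-fold) rested on 5 and 22 UMIs and on 8 and 29, with intervals that include 1. The microglia homeostasis list stood at 0.30 on 7 members, and 18 of 19 ribosomal protein genes were higher (0.15). In T-like cells, 15 of 16 cell cycle genes were lower (median -1.17, -1.34 to -0.62), interferon genes were lower (16 of 19, -0.28) and hypoxia and glycolysis genes were lower (11 of 16, -0.23); for Hmgb2 (0.538-fold), 64 of 270 sham UMIs lay in 1 cell. In NK-like cells the inflammatory list was -0.35, with the chemokine Ccl4 at 0.341-fold, the alarmin list -0.34 and the ribosomal list -0.11.

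MHC class II genes were higher after MI in T-like cells (7 of 8 members, median 0.50) and NK-like cells (7 of 8, 0.59), the reverse of B-like cells, at levels far under those of B-like cells: Cd74 was 603 CPM in T-like cells of the MI library and 13191 CPM in B-like cells. The 9 B cell markers together were also higher in MI, at 1.67-fold in T-like and 1.54-fold in NK-like cells. The glucocorticoid receptor gene Nr3c1 was 1.22-fold in neutrophil-like cells of the MI library (0.913 to 1.63). Il1b stood at 1147 and 1214 CPM there, and Cxcl2 at 4.72 and 14.5 CPM on 8 and 29 UMIs. Of the 29 sham Cxcl2 UMIs, 17 lay in 2 cells. Without the 2 richest cells of each library Cxcl2 was 0.493-fold (0.136 to 1.50). In all, 29 of 90 lists computed over 6 blood classes stood in the outer 5% on either side, 21 of them in the lower one. If lists were random, 9.0 would be expected. Random lists hold unrelated genes, while members of a list can vary together, so the excess alone is not evidence of an effect of MI. Keeping only barcodes with at least 500 genes moved the neutrophil-like share to a log2 ratio of -0.13 and the interferon list of those cells to 0.43, and a finer clustering moved the share to -0.50.

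The comparison of blood after MI with and without sleep fragmentation asks what broken sleep adds to the circulating response. Classical monocyte-like cells were 7.07% of leukocytes in MI+SF (411 cells; interval 6.42 to 7.76%) and 4.72% in MI, 1.50-fold (log2 ratio 0.58, interval 0.36 to 0.81), which put the MI+SF library near the sham library. T-like cells were lower, at 6.86% and 9.38%, 0.732-fold (-0.45, -0.63 to -0.27). Neutrophil-like cells held 21.4% in MI+SF and 17.4% in MI (0.30, 0.19 to 0.41). Both blood comparisons use the same MI library, so a trait of that library alone would give opposite directions in the 2 comparisons. A return toward sham therefore cannot be told apart from such a trait. MHC class II genes were higher in B-like, T-like and classical monocyte-like cells, and immediate early genes were higher in neutrophil-like cells. The 9 B cell markers together were also higher in T-like (1.36-fold) and classical monocyte-like cells (1.34-fold).

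Nonclassical monocyte-like cells were 4.23% in MI+SF and 4.93% in MI (log2 ratio -0.22, interval -0.47 to 0.03), and B-like cells 46.4% and 43.6% (0.09, 0.03 to 0.15). The unnamed B and platelet cluster was 9.10% against 15.04%, platelet-like barcodes were 5.51% against 11.9% of kept barcodes, and erythroid-like barcodes 12.2% against 6.99%. The direction of the neutrophil-like share depended on processing: it was -0.18 with at least 500 genes per barcode and -0.08 at a finer clustering. The class had a median of 467 genes in MI and 407 in MI+SF, below the limit of 500. At that limit 376 MI and 295 MI+SF cells of the class remained. The direction for B-like cells also turned under other filters, as did that of erythroid-like barcodes at 100 genes (-0.27).

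All 12 measured MHC class II genes were higher in B-like cells of the MI+SF library (median 0.17, 0.16 to 0.21; percentile 98.2; 0.09 without the highest doublet scores), as were 9 of 9 in T-like cells (0.38, 0.16 to 0.56), and 11 of 12 in classical monocyte-like cells (0.32, 0.16 to 0.53). In NK-like cells the median was 0.28 (-0.07 to 0.56; 5 of 8 higher), and -0.14 without the cells of highest doublet score. The 9 B cell markers together were also higher in MI+SF, at 1.36-fold in T-like, 1.39-fold in NK-like and 1.34-fold in classical monocyte-like cells. In the monocyte-like cells Cd74 stood at 3927 CPM against 2419, 1.62-fold (1.55 to 1.70), and H2-Eb1, a class II beta chain, was 1.58-fold. In B-like cells Ifi30, a lysosomal thiol reductase that prepares antigens, was 1.31-fold and Cd74 1.16-fold. B-like cells lay in cluster 1 (57.4% in MI, 47.3% in MI+SF) and cluster 4 (39.9% and 49.7%), where the list was 0.20 and 0.19. The class II level of T-like cells was again far under that of B-like cells, at 785 against 15244 CPM of Cd74.

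B-like cells of the MI+SF library had higher Il4i1, a secreted amino acid oxidase that dampens T cells (chromosome 7, 44816387 to 44840809), at 45.9 CPM against 23.9 in MI and 31.6 in sham, 1.92-fold that of MI (1.51 to 2.47). Cirbp, a cold-inducible RNA-binding protein, was 112 CPM against 71.6, 1.57-fold (1.36 to 1.81), and Smim20 1.72-fold, Pigc 2.23-fold, Pafah1b2 1.96-fold and Pafah1b3 1.52-fold. Slmap (0.434-fold, 0.292 to 0.634), the fatty acid elongase Elovl5 (0.443-fold), Ube2q2 (0.438-fold), Zfp597 (0.457-fold), Dhdds (0.431-fold) and Ankrd28 (0.467-fold) were lower, on 23 to 95 UMIs per library. The glucocorticoid response list was lower in B-like cells (-0.14, 9 of 12 members), with Fkbp5 at 0.744-fold, and in NK-like cells (-0.33, 7 of 10). The alarmin list of B-like cells stood at 0.55 on 6 members, 30 of its 54 S100a9 UMIs lay in 1 cell, and 14 neutrophil markers together were 2.75-fold (20.8 against 7.57 CPM).

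In neutrophil-like cells the largest ratios came from 6 genes whose UMIs sat in very few cells: Gsto1 (818 against 11 UMIs), Ltf, the iron-binding granule protein lactoferrin (686 against 13), and Prss27, Psca, Plet1 and Mal (91 to 152 UMIs against 0, at least 24.9-fold by a floor of 3 counts per library). The 2 cells with the most of them held 96.0% of these UMIs. Genes named as lower were Tmem131 (0.349-fold), Arhgap18 (0.404-fold), Tnks2 (0.395-fold), Lsm14a (0.430-fold), Kif23 (0.517-fold) and the platelet chemokine Ppbp (0.638-fold, 0.579 to 0.702); the 8 platelet markers together were 0.714-fold. The median of all genes was shifted by -0.11 in these cells. Haemoglobin took 49.1% of their UMIs in MI+SF and 45.4% in MI, which alone gives a shift of -0.10. Immediate early genes were higher in 16 of 19 cases (median 0.20, 0.11 to 0.34, or 0.31 against the shift; percentile 99.96), with Fos at 1.31-fold and Junb at 1.24-fold (1.16 to 1.33). Cxcl2, a neutrophil-attracting chemokine (chromosome 5, 90903871 to 90905938), stood at 71.7 against 4.72 CPM, 15.2-fold (7.50 to 35.8), on 148 and 8 UMIs, of which 51 of the 148 lay in 1 cell. Without the 2 cells with the most in each library, 50 and 5 UMIs remained (8.20-fold, 3.29 to 26.4).

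The neutrophil maturation and trafficking list, which holds the chemokine receptors and adhesion molecules that time release from marrow and ageing in blood, had 9 of 15 members lower in MI+SF (median -0.14, -0.22 to -0.00; percentile 16.6), stood at -0.03 against the shift, and was 0.03 at a finer clustering. The alarmin list (0.06, 9 of 16 higher) and the lipid and wound list (0.14, Apoe 1.72-fold) stood in the upper 5%. Inflammatory genes of classical monocyte-like cells did not differ detectably, with 10 of 17 members higher and a median of 0.06 (-0.19 to 0.25; percentile 80.8). Ccr2 was 542 and 544 CPM in these cells. The cytotoxic list stood at 1.75 there on 5 members, where Ccl5 was 3.35-fold on 92 and 20 UMIs, and 33 and all 20 of these lay in 1 cell.

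In T-like cells, cell cycle genes were higher (14 of 16 members, median 1.41, 0.66 to 1.71), with Hmgb2 at 1.87-fold and Ube2c at 4.07-fold, for which 23 of 67 UMIs lay in 1 cell. Cytotoxic genes were also higher in T-like cells (9 of 10, 0.31, 0.20 to 0.50), with Gzma, a killer cell protease, at 2.37-fold and Ccl5 at 1.28-fold, as were the hypoxia list (0.27), the lipid list (0.69) and the disease-associated microglia list (0.50). In nonclassical monocyte-like cells, interferon genes were lower (14 of 16, -0.34), all 8 measured receptors for sleep, stress and autonomic signals were lower (-0.47, -0.72 to -0.07), with Il6ra at 0.802-fold, and alarmins were higher (7 of 8, 0.40), with S100a9 at 2.41-fold and 14 neutrophil markers together at 2.05-fold. Ribosomal protein genes were higher in NK-like cells (19 of 19, 0.17) and slightly higher in nonclassical monocyte-like cells (0.09, or -0.01 without the cells of highest doublet score). The maturation list was lower in NK-like cells (-0.27). Of 90 lists, 23 stood in the outer 5%, with 18 in the upper one, where 9.0 would be expected for random lists of unrelated genes.

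**Figure D2:**
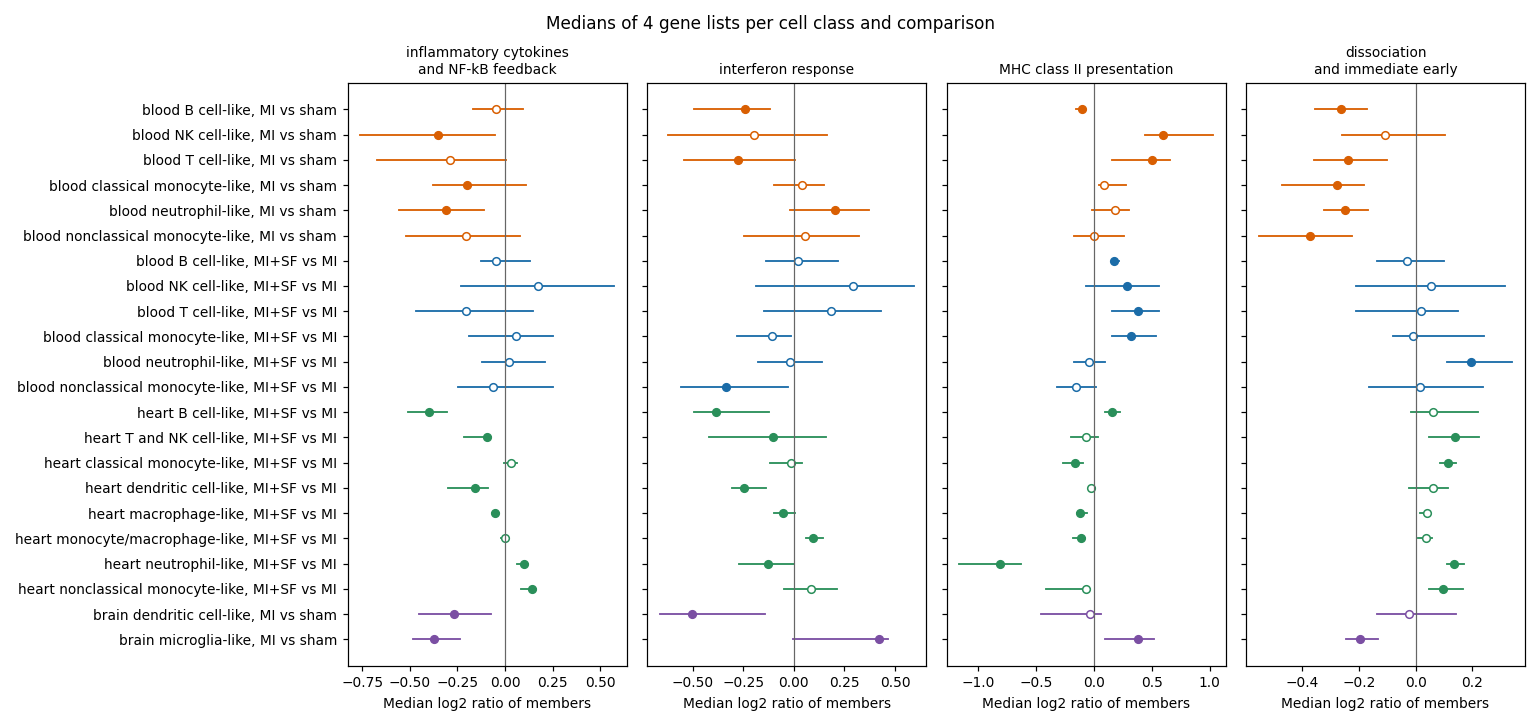
Median log2 ratio of 4 gene lists (inflammatory and NF-kB, interferon, MHC class II, immediate early) on the horizontal axes, whose scales differ between panels, for each class and comparison; lines are 95% counting intervals, and filled points stand in the outer 5% of matched random lists. Immediate early genes lie below 0 in blood of MI against sham (median -0.28 in classical monocyte-like cells), and MHC class II genes lie above 0 in blood of MI+SF against MI (0.32 in the same class) but below 0 in that class in heart (-0.17).

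The comparison of infarcted heart tissue with and without sleep fragmentation asks whether broken sleep goes with a different infiltrate. The makeup of the infiltrate was nearly the same: over the 22 clusters of at least 100 cells the median absolute log2 ratio was 0.09, where counting error alone gives 0.07. Neutrophil-like cells were 20.9% of leukocytes in MI+SF and 19.2% in MI (log2 ratio 0.12, interval 0.04 to 0.20), and classical monocyte-like and macrophage-like cells together 53.4% and 55.2% (-0.05, -0.09 to -0.01). In UMIs summed over each class, MHC class II genes were lower in classical monocyte-like and mixed cells. Hypoxia and glycolysis genes were slightly higher in these and in macrophage-like cells, and cell cycle genes were higher in the macrophage-like class as a whole.

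Macrophage-like cells were 29.6% of leukocytes in MI and 29.1% in MI+SF, mixed monocyte and macrophage-like cells 15.3% and 14.9%, and dendritic-like cells 5.03% and 5.04%. Nonclassical monocyte-like cells were lower, at 3.46% and 2.47% (log2 ratio -0.48, -0.73 to -0.24), although this turned to 0.58 at a finer clustering, and T and NK-like cells were 2.57% and 2.05% (-0.33, -0.60 to -0.05). Both libraries passed CD45 bead selection, and the MI+SF library was deeper per cell, with a median of 12184 against 8071.5 UMIs in macrophage-like and 1652 against 1046 in neutrophil-like cells.

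Macrophage-like cells of the MI+SF library had 16 of 19 cell cycle genes higher (median 0.14, 0.10 to 0.17; above all 10000 random lists), with the DNA-untangling enzyme Top2a at 1.22-fold (1.16 to 1.28) and Mcm6, a replication helicase subunit, at 1.15-fold. Histone genes made in S phase were among those named as higher: Hist2h2bb was 2.20-fold (1.84 to 2.63), Hist1h2bb 2.14-fold and Hist1h2bn 2.01-fold. Hypoxia and glycolysis genes were higher in 18 of 19 cases (0.08, 0.06 to 0.12), among them Pgk1 at 1.13-fold and Pkm at 1.11-fold. The MHC class II list was lower in 11 of 12 members (-0.12, -0.15 to -0.06), with H2-Ab1 at 0.870-fold. Cluster 3, which class II genes lead, held 17.1% of these cells in MI and 14.1% in MI+SF, and with equal shares of UMIs per cluster in both libraries the class II list was level (-0.01), the cell cycle list 0.07 and the hypoxia list 0.09. Within clusters, the cell cycle median ran from -0.31 in cluster 17 to 0.22 in cluster 5. The 9 B cell markers together were 0.689-fold in macrophage-like cells. The protease gene Ctsk was 3.40-fold and the metallothionein Mt3 3.96-fold, but 369 of 946 Ctsk UMIs and 99 of 162 Mt3 UMIs lay in 1 cell, as did 144 of 520 UMIs of Hist1h3e.

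Inflammatory and NF-kB feedback genes of macrophage-like cells were lower by very little, with 16 of 26 members lower and a median of -0.06 (-0.07 to -0.03; percentile 0.10), and with equal cluster shares the median was 0.00. The chemokine Ccl3 was 0.777-fold and Ccl4 0.852-fold, while Cxcl3 was 1.22-fold. Tnf (0.957-fold), Il1b (0.954-fold), Cxcl2 (0.968-fold), Il6 (0.940-fold) and Ccl2 (0.892-fold) were close to level. The resident and reparative list showed no difference that counting error excludes (-0.02, -0.07 to 0.00; percentile 11.1). Penk, the precursor of enkephalin opioid peptides (chromosome 4, 4133531 to 4138819), was 0.319-fold on 17 and 86 UMIs, the eosinophil-attracting chemokine Ccl24 0.703-fold (0.614 to 0.803), the growth factor Areg 0.759-fold (0.715 to 0.807), the mitochondrial leucyl-tRNA synthetase gene Lars2 0.776-fold, Sap25 0.664-fold and Gsg1 0.582-fold. Interferon (-0.05), alarmin (-0.06), maturation (-0.05), disease-associated microglia (-0.06), cytotoxic (-0.56, 5 members) and ribosomal protein lists (-0.05) stood in the lower 5%.

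Neutrophil-like cells of the MI+SF library had 18 of 26 inflammatory genes higher (median 0.10, 0.07 to 0.12; percentile 98.8), led by the alarm cytokine Il1a at 1.41-fold (1.31 to 1.50) and its receptor antagonist Il1rn at 1.22-fold. Cxcl2 was 1.07-fold, Il1b 1.01-fold and Tnf 1.09-fold. Immediate early genes were higher in 17 of 19 cases (0.14, 0.11 to 0.17), with Jun at 1.27-fold and Egr1 at 1.19-fold. Interferon genes were lower in 14 of 22 (-0.13, -0.27 to 0.00, percentile 3.25), with Ifit1 at 0.626-fold and Rtp4 at 0.737-fold. An unnamed cluster led by interferon genes, whose best marker match was neutrophil (159 MI and 74 MI+SF cells), lies outside this class. Phospho1 (1.54-fold), Yme1l1 (1.92-fold), Ormdl1 (1.92-fold), Mmgt1 (2.01-fold) and Exoc7 (1.92-fold) were named as higher, and the acute phase gene Saa3 (0.510-fold), Lars2 (0.645-fold), Ss18l2 (0.475-fold), Atxn7l3 (0.524-fold), Timm17a (0.623-fold) and Tspo (0.743-fold) as lower.

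Genes that belong to macrophages and antigen-presenting cells were lower in heart neutrophil-like cells of the MI+SF library, and 11 macrophage marker genes together were 593 against 1052 CPM there. MHC class II genes were lower in 11 of 11 (median -0.81), the reparative list in 11 of 13 (-1.03), the lipid and wound list in 17 of 19 (-0.46), the disease-associated microglia list in 15 of 17 (-0.22) and ribosomal protein genes in 18 of 19 (-0.15). Dendritic-like cells had lower lists too, with the reparative list at -1.11 (14 of 16), lipid and wound at -0.61, disease-associated microglia at -0.43, alarmins at -1.05, maturation at -0.26, interferon at -0.24 and inflammatory genes at -0.16. Their Gpnmb was 0.255-fold and Cxcl2 0.565-fold. In dendritic-like cells the 11 macrophage markers together were 0.584-fold and the 14 neutrophil markers 0.726-fold. B-like cells had lower alarmin (-0.95, 12 of 13), disease-associated microglia (-0.54), maturation (-0.49), lipid (-0.48), inflammatory (-0.40, 20 of 26) and interferon genes (-0.38), with S100a9 at 0.202-fold, and higher MHC class II genes (0.16, 9 of 12; Cd74 1.21-fold). Neutrophil markers together were 0.266-fold in these cells and macrophage markers 0.803-fold, and cluster 10 held 21.6% of them in MI and 13.6% in MI+SF. With equal shares of UMIs per cluster, the inflammatory list was -0.24, the lipid list -0.26, the disease-associated microglia list -0.35 and the class II list 0.07.

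In classical monocyte-like cells of the heart, MHC class II genes were lower in 10 of 12 (median -0.17, -0.27 to -0.10), with H2-Eb1 at 0.730-fold, hypoxia and glycolysis genes were higher in 15 of 19 (0.14), with Slc2a1 at 1.22-fold, and receptors for sleep, stress and autonomic signals were higher in 10 of 11 (0.26, 0.10 to 0.35), with the prostaglandin receptor Ptger2 at 1.69-fold and Tnfrsf1a also higher. Il6 was 0.799-fold, Ccl2 0.820-fold and Ccr2 0.998-fold. Neutrophil markers together were 0.605-fold in these cells, macrophage markers 0.930-fold and B cell markers 0.657-fold, the last with an interval that includes 1. Immediate early genes were 0.12, and the disease-associated microglia (-0.09) and ribosomal protein lists (-0.10) were lower. Mixed monocyte and macrophage-like cells had 21 of 24 interferon genes higher (0.10), with Irf7 at 1.23-fold, but the median was 0.14 in cluster 9 and -0.11 in cluster 11, and 0.01 with equal shares of cells per cluster. They had class II genes lower (-0.11; H2-Eb1 0.661-fold; B cell markers together 0.643-fold and neutrophil markers 0.595-fold), cell cycle genes lower (-0.16), hypoxia genes higher (0.08) and lipid (-0.08), disease-associated microglia (-0.09) and ribosomal lists (-0.09) lower.

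Nonclassical monocyte-like cells of the heart had 21 of 26 inflammatory genes higher (median 0.14, 0.08 to 0.16), with Il1a at 1.47-fold and Nfkbie at 1.46-fold, and receptors for sleep, stress and autonomic signals higher in 8 of 9 (0.35), with Il6ra at 1.48-fold. They were the class where the circadian clock list reached the outer 5% (0.24, 0.03 to 0.53; 11 of 14 higher), with the clock repressors Nfil3 at 1.19-fold and Bhlhe40 at 1.18-fold and Per1 at 0.887-fold. Immediate early genes were 0.10, and lipid (-0.20), glucocorticoid (-0.10), alarmin (-0.11), disease-associated microglia (-0.10) and reparative lists (-0.09) were lower. T and NK-like cells had higher glucocorticoid response (0.30, 11 of 16; Txnip 1.38-fold) and immediate early genes (0.14) and lower disease-associated microglia (-0.31), alarmin (-0.26), reparative (-0.20), lipid (-0.20), interferon (-0.10) and inflammatory lists (-0.10), with 11 macrophage markers together at 0.785-fold. Of 130 lists, 62 stood in the outer 5%, 46 of them in the lower one. With at least 500 genes per barcode the direction turned for the inflammatory list of macrophage-like cells (0.09), for Penk (0.02) and Ccl24 (0.07), and for the MHC class II list of macrophage-like cells (0.03), the interferon and cell cycle lists of mixed cells and several lists of T and NK-like, dendritic-like, B-like and nonclassical monocyte-like cells, and the neutrophil-like share was 0.41.

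The comparison of brain after MI with brain after sham surgery asks whether an infarct in the heart goes with different immune cells in the brain. Neutrophil-like cells were 1.96% of brain leukocytes in MI (127 cells) and 3.002% in sham (39 cells; log2 ratio -0.62, interval -1.13 to -0.11), and B-like cells 0.878% and 1.69% (-0.95, -1.65 to -0.24). Microglia-like cells, the resident macrophages of brain tissue, made up 83.6% (82.7 to 84.5%) and 80.9% (78.7 to 83.0%; 0.05, 0.01 to 0.09). Microglia-like cells of the MI library had lower inflammatory, glucocorticoid response and immediate early genes and higher ribosomal protein genes, the last of which were also higher in brain cells outside the leukocytes. Classical monocyte-like cells, with 65 cells in MI and 18 in sham, were 1.00% and 1.39%, a difference that was not detectable at this depth (-0.47, -1.22 to 0.28).

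T and NK-like cells were 3.61% in MI and 3.70% in sham, border macrophage-like cells 2.11% and 2.31%, and dendritic-like cells 5.73% and 5.23%. The bead selection and density gradient let other brain cells through: neuron-like barcodes were 19.99% of kept barcodes in MI and 5.47% in sham, and choroid or ependymal-like barcodes 7.99% and 15.4%. Over all kept barcodes the microglia-like share was lower in MI (-0.10). With at least 500 genes per barcode the neutrophil-like log2 ratio was 0.22 (120 MI and 21 sham cells), with an interval that includes 0 (-0.44 to 0.88).

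Inflammatory cytokine and NF-kB feedback genes were lower in microglia-like cells of the MI library in 20 of 23 cases (median -0.37, -0.48 to -0.24; percentile 0.01). Without the 2 cells with the most UMIs of each gene in each library the median was -0.17, and without the richest 0.2% of cells it was -0.34. Leaving out 2 cells takes a larger part of the 1051 sham cells than of the 5426 MI cells, which by itself moves ratios upward. Nfkb1 was 0.622-fold and Ccl2 1.02-fold. Il1b was 7.78 against 17.2 CPM, but 19 of its 23 sham UMIs lay in 2 cells, and without the 2 richest cells its ratio was 1.99-fold (0.737 to 7.54). Tnf was 0.756-fold (0.657 to 0.873), and 0.878-fold without such cells (0.753 to 1.03). Glucocorticoid response genes were lower in 13 of 15 (-0.33, -0.45 to -0.17), with Per1 at 0.532-fold and the metal-binding Mt1 at 0.739-fold, and immediate early genes in 15 of 19 (-0.20, -0.24 to -0.13; -0.31 to -0.08 under other processing), with Fosb at 0.605-fold and Atf3 at 0.686-fold. The cells of both libraries lay in different clusters: cluster 4, with a median of 709 UMIs, held the largest part of those of MI (2064 of 5426, 38.0%), and cluster 1 that of sham (289 of 1051, 27.5%). Within the 5 clusters with at least 50 cells per library, the inflammatory median ran from -0.48 in cluster 1 to -0.25 in cluster 4. Its interval included 0 in clusters 4 (-0.90 to 0.08) and 6 (-0.53 to 0.12). The immediate early median was 0.05 in cluster 6 and below 0 in the others.

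Homeostatic microglia genes, such as the purine receptor P2ry12 and Tmem119, had 11 of 15 members lower (median -0.10, -0.14 to -0.06; percentile 8.42). Within clusters this list was -0.35 in cluster 4 and between -0.04 and 0.07 in the other 4. Interferon genes were higher in 16 of 21 (0.42, -0.00 to 0.47), with Irf7 at 1.48-fold, but their median was below 0 in clusters 1, 6 and 12. MHC class II genes were higher in 8 of 11 (0.38, 0.10 to 0.52), with Cd74 at 1.96-fold and H2-Eb1 at 6.81-fold on 202 and 4 UMIs, of which 61 lay in 1 cell, but within the 5 clusters the median ran from 0.04 to 0.21, with intervals that include 0. Disease-associated microglia genes were higher in 12 of 18 (0.16, 0.08 to 0.25), with the chemokine Ccl6 at 1.41-fold. This list was also higher in choroid-like (0.42), endothelial-like (0.60) and mural-like cells (0.62). Ribosomal protein genes were higher in 17 of 19 (0.29, 0.24 to 0.31), and also in choroid-like (0.45) and endothelial-like cells (0.40). The hypoxia list was 0.19, the alarmin list -0.81 (14 neutrophil markers together were 0.692-fold) and the reparative list -0.33, with Mertk, a receptor for clearing dead cells, at 0.644-fold and Selenop at 0.638-fold. Nr3c1 (1.07-fold) had an interval that includes 1.

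The genes named as lower in microglia-like cells of the MI library were Ftl1-ps1, a ferritin light chain pseudogene (chromosome 13, 74399694 to 74407346), at 56.2 against 377 CPM (0.149-fold, 0.132 to 0.168), the stress cytokine Gdf15 at 0.222-fold, Hypk at 0.242-fold, the ATP synthase subunit gene Atp5k at 0.294-fold, the histone gene Hist1h4d at 0.330-fold and Lars2 at 0.432-fold. For Gdf15, 28 of 57 sham UMIs and 29 of 94 MI UMIs lay in 1 cell each, and without the 2 richest cells its log2 ratio was -0.92. Ftl1, the ferritin light chain gene itself, was 0.085 in log2 ratio in the same cells. Genes named as higher were Cox4i1 (1.68-fold, 1.55 to 1.82) and Cox6a1 (1.66-fold), subunits of cytochrome c oxidase, Gpx4, which protects membranes from lipid peroxidation (1.64-fold, 1.48 to 1.83), Mpnd (2.34-fold), Tmem80 (4.01-fold on 119 and 4 UMIs) and Bhlhb9 (3.12-fold). All of these but Bhlhb9 were also higher in choroid, endothelial, mural and fibroblast-like cells together, with Cox4i1 at 0.42, Gpx4 at 0.42 and Cox6a1 at 0.19 in log2 ratio. Transcripts of other cells in the microglia-like cells also differed, since 6 choroid markers together were 26089 CPM in MI and 12525 in sham, and 6 neuron markers 53.2 and 13.5 CPM.

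Dendritic-like cells of the brain had lower interferon (16 of 21, median -0.50), inflammatory (16 of 24, -0.27), alarmin (-0.40) and reparative macrophage genes (12 of 15, -0.77) in MI, with the mannose receptor Mrc1 at 0.387-fold (0.284 to 0.536) and the interferon-induced Ifi27l2a at 0.440-fold, and 10 border macrophage markers together were 0.596-fold. Ccl2 was 0.437-fold (0.345 to 0.560), but 0.706-fold without the 2 richest cells (0.504 to 1.02). Those 2 cells were a larger part of the 68 sham cells than of the 372 MI cells, which by itself moves the ratio upward. Homeostatic microglia genes were higher in 14 of 15 (0.98, 0.71 to 1.27), with P2ry12 at 3.62-fold, Sparc at 3.72-fold and 9 microglia markers together at 2.33-fold, as were the maturation (0.57), hypoxia (0.45) and cytotoxic lists (0.49). Syngr1 was 7.13-fold, Serpine2 5.10-fold and Isyna1 139 against 0 UMIs (at least 3.78-fold), and Ftl1-ps1 (0.146-fold), Lars2 (0.287-fold), Ptms (0.386-fold) and the ribosomal RNA-overlapping transcript AY036118 (0.526-fold) were lower. Retnla met the size rule with 503 against 0 UMIs, of which 479 lay in 1 cell. With at least 500 genes per barcode, P2ry12 (-0.81), Syngr1 (-2.86) and Serpine2 (-0.69) turned direction, Sparc was close to level (0.07) and Lars2 was -0.43. Without the 2 richest cells, 6 against 0 Retnla UMIs remained.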

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

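All tests of the blood and brain patterns below, and the test of UMIs per cell in the heart, were chosen only after the result was seen, while the heart tests of free RNA and doublets were written beforehand.

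In blood neutrophil-like cells, 6 genes were far higher in MI+SF than in MI, and 95.95% of their UMIs lay in 2 cells. These 2 cells had 181 UMIs of an epithelial list per 10000 against 0.810 in the other cells, with Epcam at 41 UMIs and S100a8 at 0, in line with a few epithelial cells inside the class. Without them, the 5 genes other than Ltf had a log2 ratio of 0.006 (interval -1.40 to 1.45), so a higher level in neutrophil-like cells at large cannot be told apart from none, because 11 and 9 UMIs remain. For Ltf, 98.53% of the remaining UMIs lay in the next 3 cells, which also held 193 Camp and 201 Ngp UMIs, and this speaks against a higher level at large. Whether a few immature neutrophils in the MI+SF blood carry biology of their own was not tested.

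In heart, genes of macrophages were lower in MI+SF in neutrophil-like cells (192 genes, median -0.87) and dendritic-like cells (86 genes, median -1.002). The 5% of MI cells with the most of these UMIs held 34.82% and 48.78% of them. These values lie between the limits set for free RNA and for doublets, so those 2 causes cannot be told apart. Spread by depth alone, the top 5% would hold 13.46% and 11.96%. In MI+SF the top 5% held 36.0% and 46.9%, against 14.4% and 11.6% by depth alone. The UMIs of these genes per cell were nearly level (log2 ratio -0.05 and -0.163) while all UMIs per cell were 0.62 and 0.61 higher in MI+SF. On average this fits a like amount of foreign RNA diluted in deeper cells, but it restates the lower CPM and the greater depth. The uneven spread over cells argues against a like amount in each droplet. A true difference in the neutrophil-like cells remains open and was not tested.

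In brain, the 6 genes named as lower in microglia-like cells had a median of -1.91 there and -1.83 in choroid, endothelial, mural and fibroblast-like cells, which speaks against a difference confined to microglia. The values also speak against a difference of the same size in all cell types, because the intervals in and outside microglia did not overlap for 3 of the 6 genes. Of these, Ftl1-ps1 was lower by less outside and Lars2 by more, while Gdf15 was -0.055 (interval -0.712 to 0.667) outside and -2.17 in microglia, or -0.92 there without the 2 richest cells of each library. What made the 5 other genes lower in both sets of cells was not tested.

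Blood and heart had opposite directions for MI+SF against MI in the following results, and the differences between tissues were not tested. The classical monocyte-like share differed by 0.72 (0.58 in blood, -0.14 in heart). Heart also had a mixed monocyte and macrophage-like class, which blood lacked, so these shares do not cover like sets of cells. Alarmin genes of B-like cells differed by 1.5 (0.55 and -0.95), and their disease-associated microglia list by 0.63 (0.09 and -0.54). In B-like cells the 14 neutrophil markers together were 2.75-fold in blood and 0.266-fold in heart. MHC class II genes of classical monocyte-like cells differed by 0.48 (0.32 and -0.17). There the 9 B cell markers together were 1.34-fold in blood and 0.657-fold in heart, the latter with an interval that includes 1. The maturation list of neutrophil-like cells differed by -0.21 (-0.14 and 0.07), but was 0.03 in blood at resolution 2.0. In nonclassical monocyte-like cells, alarmins differed by 0.51 (0.40 and -0.11, or 0.31 in heart at 500 genes), ribosomal proteins by 0.15 (0.09, or -0.0068 without the highest doublet scores, and -0.06) and receptors for sleep, stress and autonomic signals by -0.82 (-0.47 and 0.35). The 14 neutrophil markers together were 2.05-fold (blood) and 0.864-fold (heart) in nonclassical monocyte-like cells. Neuron-like barcodes, which no comparison of leukocytes uses, were 19.99% of kept barcodes in the brain MI library and 5.47% in sham.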

How the results depend on the processing

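No paired analysis was possible because each group had 1 library per tissue. Of the 18 results that the question names, 10 kept their direction under all of their alternatives and 2 of these also stayed near their value. Of the 205 values of all 18, 166 were the same, 31 moved and 8 turned, where the same means inside the counting interval of the main value, and turned means the other direction where that interval excludes 0. In the other direction lay 14 values, 6 of them where that interval includes 0. The classical monocyte-like share of blood kept its direction throughout, at -0.82 to -0.67 for MI against sham and 0.38 to 0.89 for MI+SF against MI, with 0.89 at 500 genes per barcode. Inflammatory genes of microglia-like cells ran from -0.49 to -0.17, with -0.49 at resolution 2.0 and -0.17 without the 2 richest cells of each gene. Among 237 other results with 1050 alternatives, 200 kept their direction, and 827 values were the same, 187 moved and 36 turned, with 50 in the other direction. Depth limits blood T-like, NK-like and nonclassical monocyte-like lists and the small brain sham classes most, where few UMIs per gene remain. Leaving out the 2 richest cells gave no value for Camp, Prss27, Psca, Plet1 and Mal, as no UMIs remained in a library. For all values below the cause was not tested.

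The blood neutrophil-like share (-0.29 for MI against sham, 0.30 for MI+SF against MI) was -0.13 and -0.18 at 500 genes, -0.50 and -0.0816 at resolution 2.0, and -0.43 and 0.0296 with classes from each cell's own markers. The blood class held 1055, 904 and 1245 cells (sham, MI, MI+SF), but 677, 501 and 532 at resolution 2.0 and 314, 233 and 277 from own markers. At 500 genes it held 439, 376 and 295 cells, since its median was 461, 467 and 407 genes. The heart neutrophil-like share (0.12) was 0.41 at 500 genes and 0.04 without the highest doublet scores. At 500 genes 1898 MI and 1331 MI+SF cells remained, of a class with a median of 532 and 740 genes. Heart monocyte and macrophage-like cells together (-0.05) were -0.13 at 500 genes and -0.0913 at 20% mitochondrial UMIs. The brain neutrophil-like share (-0.62) was 0.22 at 500 genes. Before that limit this class had a median of 1416 genes in MI and 573 in sham. The microglia-like share (0.05) was 0.11 from own markers and -0.10 over all kept cells.

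Interferon genes of blood neutrophil-like cells (0.20) were 0.43 at 500 genes, and their maturation list (-0.14) was 0.0341 at resolution 2.0. Inflammatory genes of heart macrophage-like cells (-0.06) were 0.0934 at 500 genes, -0.0326 at 100 genes, -0.0199 at 20% mitochondrial UMIs, -0.0327 at resolution 2.0, -0.0228 without the highest doublet scores, -0.0949 with median scaling, -0.0293 with cells weighted equally, -0.027 when thinned, -0.0721 without the 2 richest cells of each gene, and 0.0058 and 0.0042 with equal shares of cells and of UMIs per cluster. Interferon genes of heart neutrophil-like cells (-0.13) were -0.27 without the 2 richest cells. The reparative list of heart macrophage-like cells (-0.02) was -0.13 at 500 genes, 0.0168 from own markers and -0.0751 when thinned. Microglia homeostasis (-0.10) was -0.18 at resolution 2.0, -0.22 from own markers, -0.0187 with median scaling, -0.18 with cells weighted equally, and -0.041 and -0.0547 with equal shares of cells and of UMIs per cluster.

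Of the named genes, Ngp in blood was -2.24 without the 2 richest cells, and Retnla in brain has a value of -2.62 there only because 0 sham UMIs, against 6 in MI, were set to the floor of 3. At 500 genes Penk was 0.0185, Ccl24 0.0679, Syngr1 -2.86, P2ry12 -0.81 and Serpine2 -0.69. The blood B-like share for MI+SF against MI (0.09) was -0.30 at 500 genes, -0.0943 at 20% mitochondrial UMIs, -0.0562 with doublets kept, -0.0876 at resolution 2.0 and -0.0403 without the highest doublet scores. Erythroid-like barcodes for MI against sham (-0.24) were 0.062 with doublets kept and 0.14 without the highest scores, and for MI+SF against MI (0.80) they were -0.27 at 100 genes. The heart nonclassical monocyte-like share (-0.48) was 0.36 at 500 genes, 0.58 at resolution 2.0 and 0.0411 from own markers.

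Ribosomal proteins were 0.0016 at 500 genes in blood NK-like cells (-0.11, MI against sham) and -0.0068 without the highest doublet scores in nonclassical monocyte-like cells (0.09, MI+SF against MI). At 500 genes in heart, B-like inflammatory genes were 0.13; T and NK-like inflammatory genes 0.64, alarmins 0.53, the lipid list 0.65 and the disease-associated microglia list 0.41. Dendritic-like inflammatory genes were 0.0883, alarmins 0.30, the reparative list 0.43, the lipid list 0.72 and the disease-associated microglia list 0.0859. Macrophage-like MHC class II genes (-0.12) were 0.0287, and 0.0086 with equal shares of cells per cluster. At 500 genes, mixed-cell interferon genes were -0.13 and cell cycle genes 0.0455, and nonclassical monocyte-like inflammatory genes -0.0406 and alarmins 0.31.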

Other observations

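Blood of MI+SF mice was also set against sham blood directly. MHC class II genes were higher in NK-like cells (7 of 8 members, median 1.05, interval 0.70 to 1.31), T-like cells (7 of 9, 0.76, 0.42 to 0.97) and classical monocyte-like cells (10 of 12, 0.36, 0.22 to 0.62). The 9 B cell markers together were also higher there, at 545 against 255, 450 against 199 and 388 against 281 CPM. Immediate early genes were lower in B-like (14 of 16, -0.33), T-like (12 of 12, -0.28), classical monocyte-like (18 of 19, -0.26) and nonclassical monocyte-like cells (13 of 15, -0.39) but level in neutrophil-like cells (-0.00). In neutrophil-like cells, maturation genes were lower in 13 of 16 (-0.21, -0.38 to -0.13) and alarmins in 11 of 16 (-0.48). Glucocorticoid response genes were lower in B-like (8 of 10, -0.32) and T-like cells (8 of 9, -0.34). The classical monocyte-like share was close to sham (log2 ratio -0.19, -0.38 to -0.00), as was the neutrophil-like share (0.01, -0.10 to 0.11), while nonclassical monocyte-like cells stayed higher (0.59, 0.30 to 0.89) and T-like cells lower (-0.49, -0.68 to -0.31).

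Marker genes of leukocytes were higher in MI than in sham in brain cells outside the leukocytes. Whether these transcripts came from leukocytes or from the cells themselves was not tested. Choroid-like cells also differed in depth, with a median of 14464 UMIs in MI and 3154 in sham. In choroid, endothelial, mural and fibroblast-like cells together, 9 microglia markers were 2.54-fold (1597 against 628 CPM). The 14 neutrophil markers were 29.6-fold in choroid-like and 4.95-fold in endothelial-like cells, but their intervals included 1 in mural-like (1.33-fold) and fibroblast-like cells (1.56-fold). In the same cells, genes of microglia homeostasis were higher in 15 of 15 (median 1.93, interval 1.59 to 2.33), MHC class II genes in 9 of 10 (1.73, 1.48 to 2.08), alarmin and granule genes in 11 of 14 (1.33, 1.01 to 1.64) and ribosomal protein genes in 19 of 19 (0.45). The inflammatory list was 1.26 in choroid-like cells (17 of 20 higher), but its interval included 0 in endothelial-like (-0.29) and mural-like cells (0.22). The interferon list was 0.72 in choroid-like, 0.04 in endothelial-like and 0.11 in mural-like cells. A neuron-like cluster with a median of 931 UMIs held 1137 barcodes of MI and 4 of sham, and another held 939 and 99.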
